A study of Danio rerio with 13 samples.

How the data were processed

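RNA from whole zebrafish embryos was hybridised to Agilent 4x44k zebrafish arrays, 13 samples on 8 arrays and 3 slides. Per the labels, each sample is 1 dye channel. 5 arrays held a sample in both channels and 3 held 1 sample of the series; the 3 channels that belong to no sample of the series were not used. On 3 arrays of the first slide a FoxD3 sample was paired with a combined knockdown sample, with dyes swapped between arrays. On 2 arrays of the third slide a Klf4 sample in Cy3 was paired with a control sample in Cy5. The FoxD5 samples had no partner from the series and lay on 3 different slides. Groups, replicate numbers, doses and dyes were taken from the labels. The series text calls the replicates biological. The p-values of single genes rest on the spread between these samples. Those of camera, the list test described below, compare a list with the other genes, so they are no measure of the spread between samples.

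Per the file headers, spots were read with Agilent Feature Extraction 10.7.3.1, which subtracted the local background and then scaled both dyes linearly to give the processed signal, an intensity on a linear scale. The submitters' processing notes name Agilent Feature Extraction with no version. Per the labels and series text, the authors split the channels and quantile normalised them. The value table that the authors deposited holds an intensity on a linear scale, with log2 medians of 7.34 to 7.35 per sample. Its rank correlation with the scanner values was at least 0.99997. From those values after the quantile normalization used here, it differed by a median of 0.218 to 0.252 on the log2 scale. Its scale was thus settled while its exact steps stay unknown. The deposited well-above-background, saturation and uniformity flags are 0 or 1 marks set by Feature Extraction, per the file headers, and were used as other values. The annotation build named in the headers is danRer6 (Zv8), and the reference tables used here are of another assembly (GRCz12tu), so only gene names were taken from them and no coordinates are given.

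Of 45220 features 1417 control features were left out, leaving 43803, or 43603 distinct probes. Their accession, without its version, gave a current symbol for 25258 probes; 18345 were kept under the accession or contig of the file. Of 26836 probes with a curated transcript accession 24989 got a symbol. No spot used was saturated. Median spot brightness per sample was 54 to 318 over a background of 19.5 to 37. Well above background were 51.35%, 71.16% and 60.84% of probes in the FoxD3 samples, 67.99%, 70.79% and 76.51% in the combined knockdown, 65.23%, 60.8% and 75.72% in the FoxD5, 59.48% and 75.24% in the Klf4 and 60.26% and 76.14% in the control samples. The number of arrays limits the precision.

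The log2 processed signals of the 13 samples were quantile normalized together. Replicate spots of a probe were averaged, and the 30522 probes well above background in every sample of at least 1 group were kept. A gene was read from its probe with the highest mean, which left 19925 genes; the text names probes of a gene that disagree where a named gene depends on it. limma 3.58.1 in R 4.3.3 fitted group and dye as fixed terms and the shared array as a random block (consensus correlation 0.535), with a trended eBayes step and 7 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. All groups entered 1 fit, so groups of 2 share the spread estimated over all samples. A gene not well above background in any sample of a group has only a bound there, given as "at least N-fold": the bright group's mean against the dim group's mean of, per sample, the higher of the lowest signal among probes well above background and the gene's own signal.

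17 gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. They were tested with camera on ranked moderated statistics at a preset inter-gene correlation of 0.01, again with a correlation estimated from the residuals, and with fry, which is self-contained and compares no list with other genes. Written and tested sizes were: pluripotency and early transcription factors 30 and 30, BMP 35 and 32, Nodal, mesoderm and endoderm 35 and 31, dorsal organizer 30 and 27, FGF 28 and 22, Wnt 36 and 32, neuroectoderm 45 and 36, epidermal and enveloping layer 36 and 27, yolk syncytial layer 28 and 19, germ plasm 21 and 15, maternal oocyte 41 and 35, mitotic 43 and 32, p53 targets 40 and 27, stress 39 and 30, hatching gland and Klf-linked 27 and 13, apoptosis 33 and 27, and reference genes 19 and 19. Some genes stand in several lists: 13 of the pluripotency, 10 of the BMP, 9 of the dorsal organizer and 9 of the neuroectoderm genes are also in another, 7 of the maternal, 5 of the p53 and 0 of the reference genes.

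The text names, for each comparison with the control, the 8 most raised and 8 most lowered called genes with a symbol whose samples all lie on 1 side of the controls and that are well above background in both groups. It adds up to 3 called genes per list with the smallest adjusted p, and klf4, klf17, foxd3 and foxd5 in every sample. Between knockdowns the numbers were 5, 5 and 2. The text prints a part of these.

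The model fit and the list test were run on simulated data of 19793 genes. In each comparison 67, 67 and 66 of them were changed by 0.5, 1 and 2 on the log2 scale. The simulation drew values already normalized, filtered and read from 1 probe per gene, so it did not test those earlier steps. For Klf4 against control, 17.9%, 53.7% and 89.4% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered, and for FoxD3 against control 7.46%, 31.3% and 86.4%. For FoxD5 against control the shares were 7.46%, 38.8% and 83.3%, and for the combined knockdown 4.48%, 37.3% and 87.9%. Combined against FoxD3 gave 26.9%, 76.1% and 95.5%, combined against FoxD5 2.99%, 56.7% and 87.9%, and FoxD3 against FoxD5 10.4%, 59.7% and 77.3%. Of unchanged genes 0.0357% were called for Klf4 and 0.0102% to 0.0766% elsewhere. None of 17 unchanged lists was called, and a raised list, the p53 targets, was called in all 7 comparisons. With it 1 other list was called in 5 comparisons and 2 in the FoxD3 comparisons with control and FoxD5. Of the p53 genes 5 are also in another list. The simulated genes varied independently of each other, so these runs do not show how the list test behaves where genes vary together. They also changed far fewer genes than were called in the data, so the recovered shares may not carry over. Correlations and covariances between comparisons with the same controls were set against 20 simulations of unchanged groups. Counts of shared calls were set against independent lists.

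Alternatives were normexp background correction (offset 50) on the median spot signal, since the columns used hold no mean signal; scaling to the 75th percentile; the authors' table; no filter on dim probes, or probes above background in all samples; the mean over a gene's probes; no dye term; no array block; slide or replicate number as a block; only the groups compared; 1 slide only; and each sample left out in turn. Deviations from the group means correlated at 0.74, 0.884 and 0.394 in the same-numbered pairs of FoxD3 and combined samples, which share arrays, and at 0.407, 0.184 and 0.261 in those of FoxD3 and FoxD5 samples, which share none. The same-numbered FoxD3 and combined samples thus varied together, which cannot be told apart from sharing an array. Whether the numbers pair FoxD3 with FoxD5 samples is not settled. FoxD5 replicate 3 correlated more with FoxD3 replicate 2 (0.383), and same-numbered combined and FoxD5 samples gave 0.209, -0.297 and -0.202. With slide as a block, a FoxD5 contrast is read only from the FoxD5 sample on the slide of the other group. That sample is replicate 3 against the control and replicate 1 against the FoxD3 and combined knockdowns. A fit of Cy5 samples only was added after seeing the data. Some single genes are not reported here and are left out of the counts of named gene values; the gene lists and tests include all their measured genes. data.table (version 1.17.8), jsonlite 2.0.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and plots.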

Results

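Gene expression was measured in whole wild-type zebrafish embryos at 4.7 h after fertilization, near 30% epiboly, the time when the blastoderm spreads over the yolk and mesoderm, endoderm and the dorsal organizer are being set up. Embryos had been injected with a morpholino, an antisense oligonucleotide that blocks translation or splicing of its target RNA. FoxD3 and FoxD5 are forkhead transcription factors and Klf4 is a Krüppel-like zinc finger transcription factor. The FoxD3, FoxD5 and combined FoxD3 and FoxD5 knockdown groups held 3 samples each, and the Klf4 knockdown and control morpholino groups held 2 each. The dose was 8 ng per embryo for the control, FoxD3 and FoxD5 morpholinos and 4 ng for Klf4, and the combined injection held 4 ng of FoxD3 and 4 ng of FoxD5 morpholino. Each sample was a pool of 60 to 100 embryos, and the series text calls the replicates biological.

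The 13 samples were hybridised to 8 2-colour arrays on 3 slides. Between 51.3% and 76.5% of probes were well above background in a sample, and the number of arrays limits the precision. In all comparisons 19925 genes were tested. Samples of 1 group correlated at 0.966 to 0.994 across genes, pairs of samples from different knockdowns at 0.903 to 0.978, and control against knockdown samples at 0.855 to 0.969. On the first principal component, which held 52.6% of the variance, the controls lay at 128 and 143.9, the Klf4 samples at 70.4 and 72.2 and the FoxD samples between -81.9 and -14.1. FoxD5 replicate 3, at -14.1, stood apart from the other FoxD5 samples at -67.6 and -59.4. It was also the only FoxD5 sample on the slide of the controls. More of its probes were well above background, 75.72% against 65.23% and 60.8% in the other FoxD5 samples. What set it apart was not tested.

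The targeted genes were read first. The klf4 probe used had a normalized log2 signal of 6.77 ± 0.27 in the controls (SD, n = 2) and 4.76 ± 0.15 in the Klf4 knockdown (n = 2). Its fitted change was -2.81 ± 0.40 (SE; limma adjusted p = 0.00016), with 1 of the 2 knockdown samples well above background. This probe was not well above background in any FoxD3 or combined knockdown sample, where it was at least 2.36-fold and at least 5.85-fold lower than in the controls; another of the 3 klf4 probes was well above background in 1 sample of each of these groups. In the FoxD5 knockdown klf4 fell by 1.46 ± 0.43 (limma adjusted p = 0.0117). That call was lost in 3 of 25 alternatives, among them 75th percentile scaling (-0.97, limma adjusted p = 0.0803) and the fit without control replicate 2. Over the alternatives the limma adjusted p ran from 0.0029 to 0.0803. The gene lists used here name klf4 among the older symbols of klf17, so the label Klf4 alone does not settle which gene was targeted. The related gene klf17 was at 12.85 ± 0.21 in the controls and rose by 1.45 ± 0.14 in the Klf4 knockdown (limma adjusted p = 1.16e-05). Its other probes rose by 0.46 and 1.21 there. In the FoxD3, FoxD5 and combined knockdowns the klf17 probe used differed by -0.34, -0.49 and -0.65. The others differed by -1.82 and -1.23, -1.36 and -1.44, and -1.78 and -1.11. With the mean over probes klf17 was at -1.13 in the FoxD3 knockdown (limma adjusted p = 0.000383). foxd3 fell by 1.26 ± 0.26 in the FoxD3 knockdown (adjusted p = 0.00119) and fell by 1.26 ± 0.23 in the Klf4 knockdown (adjusted p = 0.000848). In the FoxD5 knockdown both foxd3 probes disagreed, with differences of 0.37 and -1.64. foxd5, the brightest of the 4 at 14.83 ± 0.14 in the controls, fell by 1.76 ± 0.28 in the FoxD3 knockdown (adjusted p = 0.000216), a call lost with slide as a block (-0.96, adjusted p = 0.0785; 1.43e-05 to 0.0785 over the alternatives). In its own knockdown foxd5 fell by 0.74 ± 0.27 (adjusted p = 0.0327).

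That last call had a limma adjusted p of 0.00111 to 0.643 over the alternatives. It was lost with slide as a block, at -0.17, a fit that reads the FoxD5 knockdown from replicate 3 alone. It was also lost for foxd5 when any 1 of these samples was left out: FoxD5 replicate 1 (adjusted p = 0.116) or 2 (adjusted p = 0.0949), control replicate 1 (adjusted p = 0.151), FoxD3 replicate 2 (adjusted p = 0.0676) or combined replicate 2 (adjusted p = 0.0633). In the combined knockdown foxd3 differed from the controls by -0.40 (adjusted p = 0.177) and foxd5 by -0.11 (adjusted p = 0.757). With slide as a block, which rests on 1 linking sample, foxd3 was at -1.19 and called (adjusted p = 0.0287), as it was in a fit of both groups only (-0.45, adjusted p = 0.0365). The labels do not say whether a morpholino acts on splicing or translation, and a translation-blocking morpholino need not lower its transcript, so these levels do not check the labels.

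**Figure D1:**
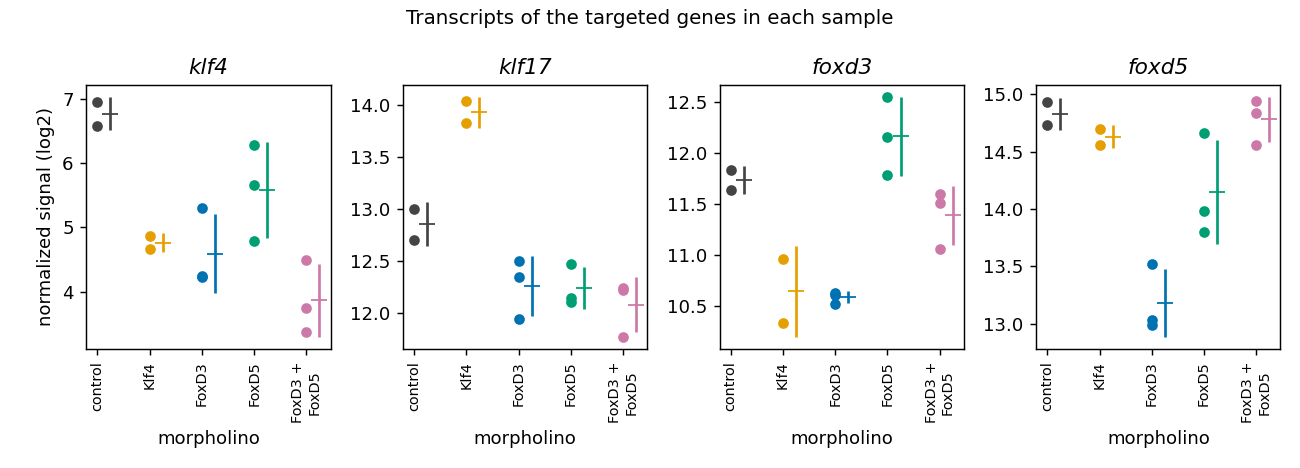
Normalized log2 signal of klf4, klf17, foxd3 and foxd5 in each of the 13 samples, by group, with group means ± SD. klf4 lay at 6.77 in the controls and at 3.86 to 5.58 in the knockdown groups, while foxd5 was at 14.83 in the controls and 13.18 in the FoxD3 knockdown.

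The first comparison asked which transcripts changed when Klf4 was knocked down. Oocyte and germ plasm RNAs were higher than in the controls, and the epidermal, dorsal organizer and Nodal, mesoderm and endoderm lists were lower. Among the highest were igfbp1a, an insulin-like growth factor binding protein (log2 change 4.25 ± 0.31, n = 2 against 2, limma adjusted p = 1.31e-06), and btg4, which recruits the deadenylase that clears maternal RNA (3.54 ± 0.19). kop, whose promoter is used to label germ cells, rose by 3.54 ± 0.27 and sybu, the kinesin linker syntabulin, by 3.34 ± 0.13 (adjusted p = 1.17e-07). The metabolic genes hsd3b7 and lipg rose by 3.29 ± 0.14 and 3.29 ± 0.20, and relch by 3.16 ± 0.14. The most lowered were pck2, a mitochondrial enzyme of gluconeogenesis (-4.38 ± 0.51, adjusted p = 3.66e-05), agr1 (-4.02 ± 0.42) and cavin2b, a caveolar coat protein (-3.59 ± 0.19). The caudal gene cdx4 changed by -3.39 ± 0.26 and msgn1 by -3.17 ± 0.26. Also lower were the transcriptional regulator prdm14 (-3.26 ± 0.54, adjusted p = 0.000501), pmepa1 (-3.18 ± 0.50) and the Wnt ligand gene wnt5b (-3.14 ± 0.53).

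Of the 35 maternal oocyte transcripts 24 rose and 2 fell in the Klf4 knockdown, with a list median of 1.11 (camera adjusted p = 1.11e-11, and 0.0032 with an estimated correlation). wee2, a kinase that holds the oocyte in meiosis, rose by 2.14 ± 0.09 and cpeb1b, a regulator of cytoplasmic polyadenylation, by 1.85 ± 0.08. Among 15 germ plasm and primordial germ cell markers 11 rose and 1 fell, with a median of 0.80 (adjusted p = 4.14e-07). The RNA-binding protein gene dazl rose by 2.65 ± 0.13 and the Tudor gene tdrd1 by 1.99 ± 0.11. The 27 epidermal and enveloping layer markers moved the other way, with 17 lower, 3 higher and a median of -0.93 (adjusted p = 1.88e-13). The enveloping layer keratin cyt1 stood at -2.26 ± 0.13, tmsb1 at -2.04 ± 0.14 and the calpain gene capn9 at -1.63 ± 0.12. Adjusted over the list alone, the counts were 25 higher and 2 lower for the maternal list, 11 and 1 for germ plasm, and 3 and 17 for the epidermal list.

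Of 27 dorsal organizer genes 16 fell and 4 rose (median -1.09, adjusted p = 2.32e-06), among them the head gene otx2b at -3.67 ± 0.28, with 1 of 2 knockdown samples above background, and foxb1a at -1.50 ± 0.15. In the Nodal, mesoderm and endoderm list 16 of 31 fell and 2 rose (median -0.53, adjusted p = 9.68e-06), with tbx16l at -2.52 ± 0.21 and efnb2b at -2.72 ± 0.25. BMP and ventral genes had 13 of 32 lower and 4 higher (median -0.42, adjusted p = 9.13e-05), among them gata2a at -1.50 ± 0.10. Wnt and posterior genes had 14 of 32 lower and 2 higher (median -0.62, adjusted p = 1.47e-05), with the receptor gene fzd10 at -1.82 ± 0.19 and sp5a at -1.39 ± 0.14. FGF signalling had 11 of 22 lower and 2 higher (median -0.56, adjusted p = 0.00231): the feedback inhibitor genes spry2 and dusp6 were at -1.08 ± 0.13 and -0.99 ± 0.15, while etv5a rose by 0.88 ± 0.11. Markers of the yolk syncytial layer had 8 of 19 lower and 3 higher (median -0.41, adjusted p = 0.0105), with the lipoprotein genes apoa1a at -2.97 ± 0.42 and mttp at -1.22 ± 0.16. Neuroectoderm genes had 15 of 36 lower and 7 higher (median -0.49, adjusted p = 0.00127), among them her3 at -2.41 ± 0.22, whereas her5 rose by 1.37 ± 0.13. The neuroectoderm call was lost with an estimated correlation (adjusted p = 0.121), and the other 9 list calls of this comparison held. When adjusted over the list alone, lower and higher genes numbered 18 and 4 for dorsal organizer, 19 and 2 for Nodal, 14 and 5 for BMP, 14 and 2 for Wnt, 11 and 2 for FGF, 8 and 3 for yolk syncytial layer, and 17 and 8 for neuroectoderm.

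The 7 other lists did not pass in the Klf4 knockdown. Their adjusted p and called members were 0.115 for pluripotency factors (6 higher, 12 lower), 0.914 for mitotic genes (10 and 5), 0.295 for p53 targets (12 and 2), 0.844 for stress genes (10 and 8), 0.994 for hatching gland and Klf-linked genes (3 and 2), 0.449 for apoptosis regulators (8 and 2) and 0.994 for reference genes (6 and 5). The pluripotency list did pass without FoxD3 replicate 1 (adjusted p = 0.0489) and without Klf4 replicate 2 (adjusted p = 0.047), within a range of 0.00863 to 0.454 over its alternatives. It also passed in a fit of both groups only (adjusted p = 0.0303) and on 1 slide (adjusted p = 0.0356), and with the mean over probes it passed (adjusted p = 0.00863) and so did mitotic genes (-0.39, adjusted p = 0.0199). Its member klf2a rose by 1.26 ± 0.10 and sall1a fell by 1.51 ± 0.14.

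Over all genes tested 8415 changed in the Klf4 knockdown, 5446 higher and 2969 lower (42.2%), of which 2692 and 1172 changed at least 2-fold; the median of all genes was 0.06. Both groups lay on 1 slide, and slide as a block gave 8706 while that slide alone, with no dye term, gave 8099. The count fell to 5063 without the array block and to 5027 without control replicate 1, 5107 without combined replicate 1, 5302 without Klf4 replicate 1 and 5548 without FoxD3 replicate 2. The estimated array correlation was 0.105 without combined replicate 1 and 0.594 without FoxD3 replicate 2, against 0.535 with all samples. Its part in these counts was not tested. All Klf4 samples were Cy3 and all controls Cy5, so the dye effect in this comparison was taken from the FoxD samples.

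The second comparison asked which transcripts changed when FoxD3 was knocked down. Germ plasm RNAs and p53 targets were higher, and the epidermal, dorsal organizer and Nodal, mesoderm and endoderm lists were lower. Maternal RNAs were higher too, a call lost with an estimated correlation. The transcription factor gene mef2d rose by 5.29 ± 0.35 (n = 3 against 2, limma adjusted p = 2.31e-07), the p53-induced killer gene bbc3 by 4.44 ± 0.34 and the stress sensor gadd45aa by 4.27 ± 0.25. znf296, mtus1a and the growth factor gene hbegfb rose by 4.40 ± 0.57, 4.38 ± 0.15 and 4.34 ± 0.33. The chaperone gene hsp90aa1.2 fell by 6.72 ± 0.50 and serpinh1b, the collagen chaperone, fell by 6.12 ± 0.35. Lower too were the keratin genes krt99 (-5.71 ± 0.17, adjusted p = 4.36e-09) and krt17 (-5.33 ± 0.33), the Wnt target sp5l (-5.12 ± 0.22), slc38a4 (-4.97 ± 0.15) and lcp1, an actin-bundling protein (-4.68 ± 0.26).

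Of 27 p53 targets 20 rose and 3 fell in the FoxD3 knockdown, with a median of 1.13 (camera adjusted p = 2.6e-05, and 0.00898 with an estimated correlation). sesn1, a stress-induced sestrin, rose by 3.89 ± 0.14 (adjusted p = 9.68e-09), and bbc3 and gadd45aa rose as above. By fry, which tests whether the genes of a list move one way on balance, the p53 list gave an adjusted p of 1.52e-06. As fry compares no list with other genes, and 57.8% of all genes were called here, this value does not set the p53 list apart. The 27 apoptosis regulators, with 9 higher and 7 lower, did not pass (median 0.14, adjusted p = 0.71); birc2, an inhibitor of apoptosis, fell by 2.33 ± 0.17. Stress and immediate early genes did not pass either (12 higher and 11 lower of 30, median -0.11, adjusted p = 0.703), although their member fosab rose by 3.63 ± 0.23; in a fit of both groups only they passed as lower (-0.25, adjusted p = 0.0278). With p adjusted over the list alone, the p53 counts were again 20 and 3, against 9 and 7 for apoptosis and 12 and 12 for stress.

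Maternal oocyte transcripts had 26 of 35 higher and 3 lower in the FoxD3 knockdown (median 1.23, adjusted p = 3.06e-05; adjusted p = 0.0705 with an estimated correlation). gdf9, an oocyte growth factor, rose by 2.80 ± 0.14, wee2 by 2.15 ± 0.11 and cpeb1b by 1.96 ± 0.10. Germ plasm markers had 11 of 15 higher and 2 lower (median 0.85, adjusted p = 0.00123), with dazl at 2.46 ± 0.15 and tdrd1 at 2.28 ± 0.12. In the epidermal and enveloping layer list 18 of 27 fell and 3 rose (median -1.36, adjusted p = 6.59e-11): cyt1 was at -4.67 ± 0.15 and krt92 at -3.36 ± 0.15, while foxi1, a factor of ionocyte and ventral ectoderm that stands in the BMP list, rose by 2.37 ± 0.12. Yolk syncytial layer markers had 11 of 19 lower and 3 higher (median -1.18, adjusted p = 0.000224), among them gata6 at -2.37 ± 0.16 and mttp at -2.57 ± 0.18. If adjusted over the list alone, higher and lower genes numbered 26 and 3 for maternal, 11 and 2 for germ plasm, 3 and 18 for epidermal, and 4 and 11 for yolk syncytial layer.

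The Nodal, mesoderm and endoderm list had 25 of 31 lower and 3 higher in the FoxD3 knockdown (median -1.47, adjusted p = 4.96e-14). The endoderm-specifying factor genes sox32 and gata5 were at -3.82 ± 0.16 and -2.60 ± 0.15. Dorsal organizer genes had 19 of 27 lower and 5 higher (median -1.76, adjusted p = 1.06e-08), with lhx1a at -3.62 ± 0.26 and the Wnt antagonist gene dkk1b at -1.97 ± 0.15. BMP and ventral genes had 19 of 32 lower and 5 higher (median -0.87, adjusted p = 4.3e-06); eve1 and cdx4 had fitted changes of -7.21 ± 0.30 and -7.14 ± 0.30, with 1 of 3 knockdown samples well above background. FGF signalling had 16 of 22 lower and 2 higher (median -1.30, adjusted p = 0.000231), with fgf24 at -3.10 ± 0.20, spry2 at -2.07 ± 0.15 and etv5a rising by 2.68 ± 0.13. Wnt and posterior genes had 17 of 32 lower and 6 higher (median -0.57, adjusted p = 0.00027), with fzd10 at -3.27 ± 0.21. With values adjusted over the list alone, lower and higher genes numbered 25 and 3 for Nodal, 20 and 5 for dorsal organizer, 20 and 6 for BMP, 18 and 2 for FGF and 17 and 7 for Wnt.

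Neuroectoderm genes had 16 of 36 lower and 9 higher (median -0.60, adjusted p = 0.000889; adjusted p = 0.0965 with an estimated correlation), and fezf2 was at least 24.7-fold higher, not well above background in either control. Pluripotency factors had 19 of 30 lower and 9 higher (median -0.79, adjusted p = 0.015; adjusted p = 0.179 with an estimated correlation): sox3 was at -2.32 ± 0.11, sox2 at -7.14 ± 0.35 with 1 of 3 samples above background, and klf2a rose by 2.52 ± 0.11. Mitotic genes had 12 of 32 lower and 8 higher (median -0.15, camera adjusted p = 0.00321, and 0.0705 with an estimated correlation). Their median ran from -0.85 to -0.083 over the alternatives. Among them were the replication genes mcm3 at -3.12 ± 0.19 and mcm6 at -2.82 ± 0.15 and the mitotic kinase cdk1 at -2.08 ± 0.12. Hatching gland and Klf-linked genes (1 higher, 2 lower of 13, adjusted p = 0.392) and reference genes (6 higher, 4 lower of 19, adjusted p = 0.862) did not pass, but with the mean over probes reference genes passed as lower (-0.59, adjusted p = 0.0322). Adjusted over the list alone, lower and higher genes numbered 17 and 10 for neuroectoderm, 19 and 10 for pluripotency, 12 and 8 for mitotic, 1 and 1 for hatching gland and 4 and 6 for reference genes.

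A total of 11518 genes changed in the FoxD3 knockdown, 7073 higher and 4445 lower (57.8%), with 4767 and 2933 changed at least 2-fold and a median of all genes of 0.27. No FoxD3 sample shared a slide with a control, and slide as a block, resting on the single FoxD5 sample that links them, gave 6540 genes. With that block the p53, epidermal and maternal lists had medians of 1.02, -1.32 and 1.23. Without FoxD3 replicate 1, the sample with the fewest probes above background, 11549 genes changed.

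**Figure D2:**
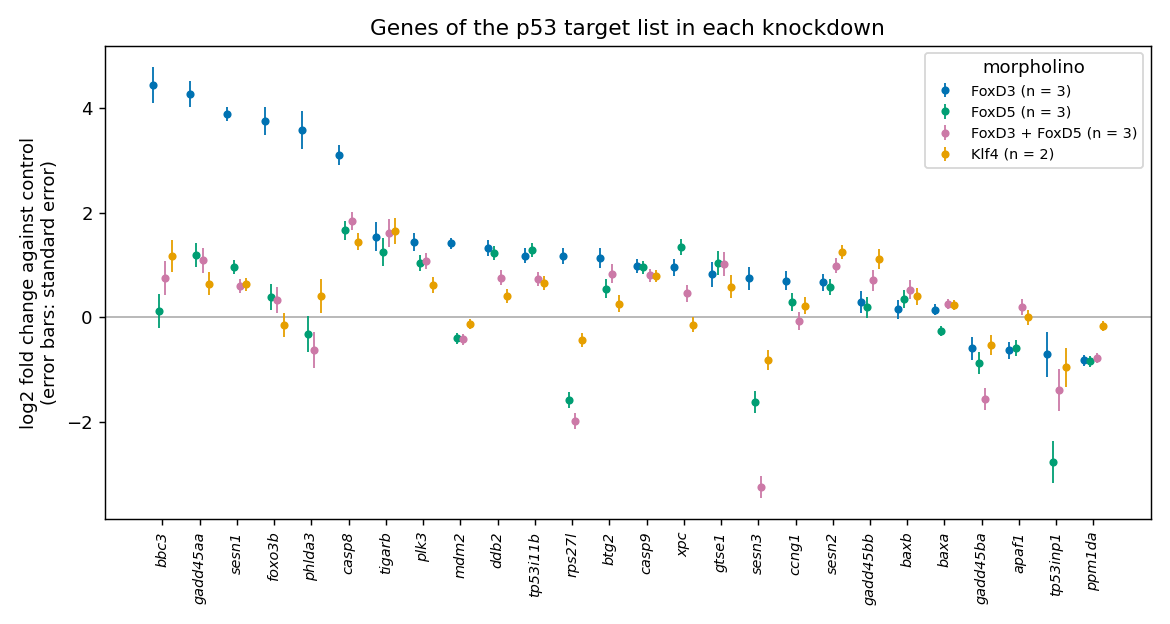
Log2 fold change against the control ± SE of genes of the p53 target list in the 4 knockdowns. bbc3 (4.44) and gadd45aa (4.27) lay highest, at the left end, in the FoxD3 knockdown, where most of the list rose.

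The third comparison asked the same of FoxD5. As in the FoxD3 knockdown, mef2d was the most raised of the named genes (5.66 ± 0.33, n = 3 against 2, limma adjusted p = 1.31e-07), followed by znf296 (4.79 ± 0.54), mtus1a (4.56 ± 0.14) and sybu (4.11 ± 0.14). b4galnt1a, pde7a and the mitotic checkpoint gene chfr rose by 4.05 ± 0.16, 3.93 ± 0.40 and 3.87 ± 0.33. The most lowered were serpinh1b (-7.70 ± 0.34, adjusted p = 2.75e-08), the neural and pluripotency factor sox2 (-6.59 ± 0.33), the ventral homeobox gene eve1 (-5.93 ± 0.28) and cdx4 (-5.39 ± 0.28). b3gnt5a, the ceramidase gene acer1, foxc1a and krt17 followed at -5.10 ± 0.31, -5.07 ± 0.32, -4.91 ± 0.52 and -4.80 ± 0.32.

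In the FoxD5 knockdown 25 of 35 maternal oocyte transcripts rose and 3 fell (median 1.19, camera adjusted p = 2.62e-05; adjusted p = 0.0674 with an estimated correlation), among them gdf9 at 2.12 ± 0.14 and cpeb1b at 1.69 ± 0.09. Germ plasm markers had 12 of 15 higher and 2 lower (median 0.75, adjusted p = 0.00228), with kop at 3.63 ± 0.29, tdrd1 at 2.42 ± 0.11 and dazl at 2.09 ± 0.15. Epidermal and enveloping layer markers had 19 of 27 lower and 2 higher (median -1.28, adjusted p = 6.59e-11), with krt5 at -3.38 ± 0.20, cyt1 at -3.21 ± 0.14 and krt92 at -2.48 ± 0.14. Markers of the yolk syncytial layer had 11 of 19 lower and 3 higher (median -0.66, adjusted p = 0.0175); gata5 was at -1.73 ± 0.14 and cebpa at -1.51 ± 0.17, but mxtx2, the layer's own homeobox regulator, rose by 1.92 ± 0.19. When adjusted over the list alone, higher and lower genes numbered 25 and 3 for maternal, 13 and 2 for germ plasm, 2 and 19 for epidermal, and 3 and 11 for yolk syncytial layer.

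The Nodal list had 23 of 31 lower and 3 higher in the FoxD5 knockdown (median -0.87, adjusted p = 5.67e-07), with tbx16l at -4.48 ± 0.23, msgn1 at -3.84 ± 0.28 and sox32 at -2.38 ± 0.15. Dorsal organizer genes had 16 of 27 lower and 5 higher (median -1.06, adjusted p = 0.000529), with lhx1a at -3.15 ± 0.25 and ism1 at -2.32 ± 0.18. ripply1, a somite regulator, was at least 14.2-fold lower and not well above background in any FoxD5 sample. BMP and ventral genes had 18 of 32 lower and 4 higher (median -0.62, adjusted p = 1.28e-05), with msx1b at -3.29 ± 0.22. FGF signalling had 13 of 22 lower and 2 higher (median -1.07, adjusted p = 0.000529), with spry2 at -1.87 ± 0.14 and ier2a at -1.51 ± 0.11. Wnt and posterior genes had 16 of 32 lower and 7 higher (median -0.28, adjusted p = 0.0125), with fzd10 at -3.28 ± 0.20 and axin1, a scaffold of the beta-catenin destruction complex, rising by 1.82 ± 0.12. With p adjusted over the list alone, lower and higher genes numbered 23 and 3 for Nodal, 18 and 5 for dorsal organizer, 18 and 5 for BMP, 15 and 2 for FGF and 16 and 7 for Wnt. The Wnt call was lost when only probes above background in all samples were kept (adjusted p = 0.0769; 0.00126 to 0.0769 over the alternatives).

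Neuroectoderm genes had 15 of 36 lower and 8 higher (median -0.41, adjusted p = 0.00454; adjusted p = 0.151 with an estimated correlation), with her9 at -3.90 ± 0.27. Mitotic genes had 14 of 32 lower and 8 higher (median -0.28, adjusted p = 0.00693; adjusted p = 0.0884 with an estimated correlation), with pcna at -2.30 ± 0.13 and cdk1 at -2.16 ± 0.11. Pluripotency factors had 16 of 30 lower and 6 higher (median -0.50, adjusted p = 0.0418; adjusted p = 0.262 with an estimated correlation), with sox3 at -1.69 ± 0.11 and the maternal factor gene sox19b rising by 2.89 ± 0.14. That call was also lost with slide as a block (adjusted p = 0.0934) and without FoxD5 replicate 3 (adjusted p = 0.0811), within a range of 0.000506 to 0.262. Stress genes had 12 of 30 lower and 6 higher (median -0.32, adjusted p = 0.0431; adjusted p = 0.0674 with an estimated correlation). The stress call was lost without FoxD3 replicate 2 (adjusted p = 0.05), Klf4 replicate 1 (adjusted p = 0.0639), Klf4 replicate 2 (adjusted p = 0.0643) or control replicate 2 (adjusted p = 0.0543), within a range of 0.00912 to 0.0868. If adjusted over the list alone, lower and higher genes numbered 16 and 8 for neuroectoderm, 14 and 8 for mitotic, 16 and 7 for pluripotency and 12 and 6 for stress.

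The p53 targets had 12 of 27 higher and 8 lower in the FoxD5 knockdown and did not pass (median 0.35, adjusted p = 0.722): casp8, which starts death receptor apoptosis, rose by 1.66 ± 0.18 and the p53-induced ribosomal protein gene rps27l fell by 1.58 ± 0.15. Apoptosis regulators (6 higher, 9 lower of 27, adjusted p = 0.402), hatching gland and Klf-linked genes (1 and 2 of 13, adjusted p = 0.398) and reference genes (5 and 4 of 19, adjusted p = 0.98) did not pass, except for reference genes with the mean over probes (-0.48, adjusted p = 0.0426). Among apoptosis regulators the median was 0.12 while the test pointed down. The adaptor gene tradd rose by 1.63 ± 0.14, and bik, a killer gene of the BCL2 family, stood at -3.91 ± 0.37 with 2 of 3 samples above background. With values adjusted over the list alone, higher and lower genes numbered 12 and 8 for p53, 6 and 9 for apoptosis, 0 and 1 for hatching gland and 5 and 4 for reference genes.

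In the FoxD5 knockdown 11742 genes changed, 6946 higher and 4796 lower (58.9%), with 4559 and 2967 changed at least 2-fold and a median of all genes of 0.23. With slide as a block this change was read from FoxD5 replicate 3 alone, the only FoxD5 sample on the slide of the controls. The fit of that slide only rests on the same sample, so these fits are not separate checks. In the latter fit the sample was assumed to vary like the Klf4 and control samples, with 2 residual degrees of freedom and no dye term. The pluripotency median was -0.34 with slide as a block, as in replicate 3 minus the control mean. Without FoxD5 replicate 3 the count was 12409.

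In the combined knockdown the epidermal and enveloping layer, yolk syncytial layer and Nodal, mesoderm and endoderm lists were lower than in the controls and maternal and germ plasm RNAs higher. mtus1a rose by 4.57 ± 0.14 (n = 3 against 2, limma adjusted p = 2.02e-09), the lipase gene lipg by 4.38 ± 0.21, kop by 4.11 ± 0.29 and tnfaip8l1 by 3.94 ± 0.34. mef2d rose by 3.85 ± 0.33, svila by 3.78 ± 0.19, the aminotransferase gene got2a by 3.78 ± 0.13 and akr1b1.2 by 3.78 ± 0.32. The largest falls were in serpinh1b (-7.46 ± 0.34), hsp90aa1.2 (-7.22 ± 0.48), eve1 (-7.08 ± 0.28), sox2 (-6.98 ± 0.33) and lcp1 (-6.85 ± 0.25). cdx4, krt17 and krt99 were at -6.80 ± 0.28, -6.17 ± 0.32 and -6.15 ± 0.16 (adjusted p = 9.01e-10 for krt99).

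Of 27 epidermal and enveloping layer markers 19 fell and 4 rose in the combined knockdown, with a median of -2.22 (camera adjusted p = 7.42e-23). cyt1 was at -5.99 ± 0.14, tmsb1 at -4.27 ± 0.15 and the annexin gene anxa1a at -3.35 ± 0.12. Yolk syncytial layer markers had 11 of 19 lower and 4 higher (median -1.33, adjusted p = 1.34e-07), with mttp at -4.05 ± 0.17 and cebpa at -3.69 ± 0.17. The Nodal list had 24 of 31 lower and 2 higher (median -1.49, adjusted p = 3.33e-14), with sox32, gata5 and gata6 at -4.19 ± 0.15, -3.25 ± 0.14 and -2.95 ± 0.15. Dorsal organizer genes had 18 of 27 lower and 4 higher (median -2.07, adjusted p = 2.98e-07), with ism1 at -4.04 ± 0.18 and dkk1b at -2.50 ± 0.14. Maternal oocyte transcripts had 28 of 35 higher and 2 lower (median 1.32, adjusted p = 1.34e-07, and 0.0199 with an estimated correlation), with btg4 at 3.51 ± 0.20 and cpeb1b at 2.24 ± 0.09. Germ plasm markers had 11 of 15 higher and 1 lower (median 1.32, adjusted p = 4.7e-05), with tdrd1 at 3.03 ± 0.11. Adjusted over the list alone, lower and higher genes numbered 19 and 4 for epidermal, 11 and 4 for yolk syncytial layer, 25 and 2 for Nodal, 18 and 4 for dorsal organizer, 2 and 28 for maternal and 1 and 11 for germ plasm.

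BMP genes had 19 of 32 lower and 5 higher (median -0.89, adjusted p = 4.68e-07), with the BMP modulator bmper at -5.40 ± 0.34 and 2 of 3 samples above background. FGF signalling had 17 of 22 lower and 2 higher (median -1.28, adjusted p = 0.000182), with fgf24 at -3.46 ± 0.19, and Wnt genes had 18 of 32 lower and 4 higher (median -0.57, adjusted p = 2.41e-05), with sp5a at -3.41 ± 0.16. Pluripotency factors had 18 of 30 lower and 6 higher (median -0.66, adjusted p = 0.000217), with sox3 at -2.05 ± 0.11 and sox19b rising by 2.76 ± 0.14. Stress genes had 16 of 30 lower and 7 higher (median -0.72, adjusted p = 0.0232). Neuroectoderm genes had 17 of 36 lower and 11 higher (median -0.38, adjusted p = 0.0114; adjusted p = 0.225 with an estimated correlation, and 0.118 with slide as a block). The other 11 list calls of this comparison held with an estimated correlation. When adjusted over the list alone, lower and higher genes numbered 20 and 5 for BMP, 17 and 2 for FGF, 18 and 5 for Wnt, 20 and 6 for pluripotency, 16 and 8 for stress and 18 and 11 for neuroectoderm.

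The p53 targets had 15 of 27 higher and 7 lower and did not pass (median 0.53, adjusted p = 0.983); casp8 rose by 1.85 ± 0.18, whereas the sestrin gene sesn3 fell by 3.24 ± 0.21. Also without a call were mitotic genes (12 higher, 10 lower of 32, adjusted p = 0.3, the median of 0.08 opposing a test that pointed down), apoptosis regulators (13 and 5 of 27, adjusted p = 0.96), hatching gland genes (1 and 3 of 13, adjusted p = 0.394) and reference genes (6 and 6 of 19, adjusted p = 0.565). Mitotic genes did pass as lower under 75th percentile scaling (-0.064, adjusted p = 0.0296) and with the mean over probes (-0.37, adjusted p = 0.015). With p adjusted over the list alone, higher and lower genes numbered 16 and 7 for p53, 12 and 10 for mitotic, 13 and 5 for apoptosis, 0 and 3 for hatching gland and 6 and 6 for reference genes. In total 11200 genes changed, 6723 higher and 4477 lower (56.2%), 4404 and 2789 of them at least 2-fold, with a median of all genes of 0.20. Slide as a block gave 7686, and no combined knockdown sample shared a slide with a control.

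**Figure D3:**
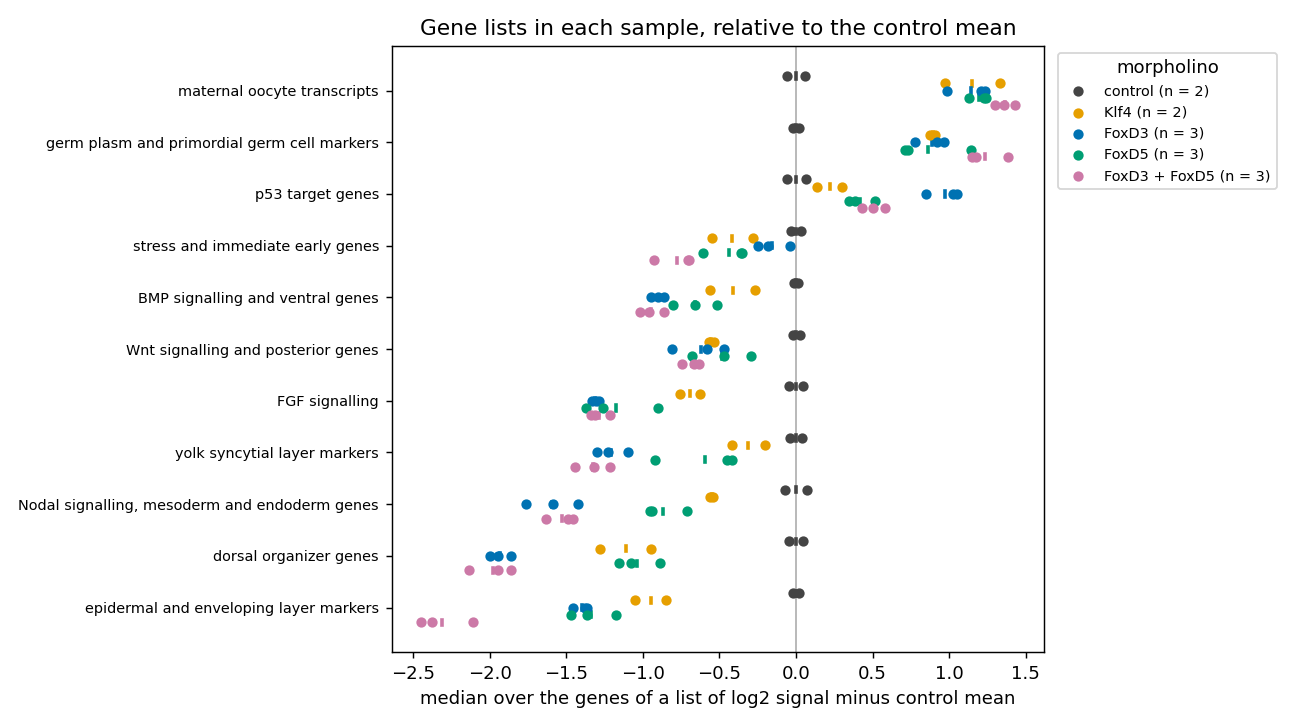
Median over the genes of 11 lists of the normalized log2 signal minus the control mean, 1 point per sample and a tick at each group mean. The maternal and germ plasm lists lay above 0 and the epidermal list below 0 in all 11 knockdown samples.

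The fold changes of the 4 knockdowns share the same 2 control samples. FoxD3 and FoxD5 knockdowns correlated at 0.905 across genes, where simulated unchanged groups that shared simulated controls gave 0.62. The correlation of the combined knockdown with FoxD3 was 0.877 (simulated 0.814), with FoxD5 0.812 (simulated 0.618) and with Klf4 0.754 (simulated 0.407). For Klf4 it was 0.587 with FoxD3 (simulated 0.499) and 0.531 with FoxD5 (simulated 0.41). The correlation of FoxD3 with the combined knockdown and with Klf4 was thus little above that of unchanged groups. Simulated correlations hold noise alone, though, so they do not give the part of an observed correlation that shared controls make up. Covariances ran from 0.617 to 1.68, against 0.0435 to 0.0986 in the simulations. For FoxD3 with the combined knockdown the covariance was 1.68 against 0.0986, and for FoxD3 with Klf4 it was 0.72 against 0.0561. In all 4 knockdowns 3654 genes were called higher and 1527 lower, where independent lists would share 227 and 36. Comparisons with the same controls are not independent, and shared calls were not simulated. The controls were too few to split, so part of the excess may come from them.

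The combined knockdown was then compared with the FoxD3 knockdown, on the same 3 arrays with swapped dyes. By list the smallest adjusted p was that of p53 targets, lower in the combined knockdown, followed by the epidermal and enveloping layer markers, lower too and with the larger median difference. lnx1, a ubiquitin ligase, differed by -4.77 ± 0.18 (n = 3 against 3, limma adjusted p = 2.48e-08), the matrix metalloproteinase gene mmp2 by -4.74 ± 0.28, mat2al by -4.33 ± 0.27, the p53 target phlda3 by -4.20 ± 0.21 and ctsh, a lysosomal cathepsin, by -4.10 ± 0.14. Among the most raised were drll.2 (2.12 ± 0.19), the mRNA export gene alyref (2.03 ± 0.19), bcl7bb (1.97 ± 0.19) and the epithelial protease gene st14a (1.92 ± 0.20).

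Of the 27 p53 targets 18 were lower and 4 higher in the combined than in the FoxD3 knockdown (median -0.57, camera adjusted p = 3.62e-20), led by bbc3 (-3.68 ± 0.20), sesn1 (-3.29 ± 0.08) and rps27l (-3.16 ± 0.09). Stress and immediate early genes had 15 of 30 lower and 4 higher (median -0.48, adjusted p = 0.000202), with fosab at -3.24 ± 0.13 and jun at -2.91 ± 0.12. Epidermal and enveloping layer markers were lower again, 18 of 27 with 4 higher (median -0.84, adjusted p = 2.8e-12), among them tmsb1 at -2.05 ± 0.09 and anxa1a at -1.72 ± 0.08. Markers of the yolk syncytial layer had 9 of 19 lower and 0 higher (median -0.46, adjusted p = 0.00097), with cebpa at -2.14 ± 0.10 and mttp at -1.49 ± 0.11. Mitotic genes were higher, 19 of 32 with 5 lower (median 0.28, adjusted p = 0.000399), with the spindle motor kif11 at 1.12 ± 0.10 and pcna at 0.89 ± 0.08. Maternal transcripts had 16 of 35 higher and 7 lower (median 0.27, adjusted p = 0.0181; adjusted p = 0.373 with an estimated correlation), with the translation factor gene eif4e1b at 0.94 ± 0.07. Pluripotency factors had 16 of 30 lower and 5 higher (median -0.31, adjusted p = 0.0109; adjusted p = 0.183 with an estimated correlation), with klf2a at -1.05 ± 0.07. With the mean over probes the pluripotency change was nearly gone (median -0.041, adjusted p = 0.733). The call was also lost with slide as a block (median -0.32, adjusted p = 0.0741) and without FoxD5 replicate 3 (median -0.31, adjusted p = 0.0612), within a range of 0.000653 to 0.733. If adjusted over the list alone, lower and higher genes numbered 18 and 4 for p53, 15 and 4 for stress, 18 and 4 for epidermal, 9 and 0 for yolk syncytial layer, 5 and 21 for mitotic, 7 and 17 for maternal and 16 and 5 for pluripotency.

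The 10 other lists did not pass: BMP (adjusted p = 0.447), Nodal (0.92), dorsal organizer (0.309), FGF (0.92), Wnt (0.227), neuroectoderm (0.187), germ plasm (0.0917), hatching gland (0.979), apoptosis (0.314) and reference genes (0.129). With no filter on dim probes the germ plasm list passed as higher (0.35, adjusted p = 0.037). Within them the ventral factor foxi1 stood at -1.55 ± 0.07, the apelin receptor gene aplnrb at -2.84 ± 0.12 and ism1 at -1.92 ± 0.11, while the chemokine receptor gene cxcr4a was higher by 1.74 ± 0.12. Between both knockdowns 9847 genes differed, 4514 higher and 5333 lower in the combined group (49.4%), with 991 and 1559 differing at least 2-fold; foxd5 was higher by 1.65 ± 0.17. Of the genes called 45.8% were higher, against 53.4% with the mean over probes (5213 higher, 4557 lower). Slide as a block gave 10312 and the 1 slide with both groups 10153, while the count was 5819 without the array block. Leaving out combined replicate 2 gave 3282, FoxD3 replicate 2 gave 3992 and combined replicate 1 gave 5683.

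Set against the FoxD5 knockdown, the combined knockdown was lower in the epidermal and enveloping layer, yolk syncytial layer and Nodal, mesoderm and endoderm lists. ndrg1b was higher by 4.09 ± 0.19 (n = 3 against 3, limma adjusted p = 2.73e-07), zbtb2a by 2.64 ± 0.24, st14a by 2.57 ± 0.28 and zdhhc15b by 2.56 ± 0.13. lcp1 was lower (-3.60 ± 0.22), as were cand2 (-3.26 ± 0.49), lrp3 (-3.20 ± 0.30) and phactr3a (-3.17 ± 0.17). fscn2b stood at -4.09 ± 0.93 (adjusted p = 0.00454), a call lost with slide as a block (-1.30, adjusted p = 0.0984) and without combined replicate 2 (-2.83, adjusted p = 0.0576; 0.000179 to 0.0984 over the alternatives).

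Epidermal and enveloping layer markers had 17 of 27 lower and 3 higher (median -0.94, camera adjusted p = 2.9e-11), with cyt1 at -2.79 ± 0.12 and anxa1a at -2.04 ± 0.11. Yolk syncytial layer markers had 10 of 19 lower and 1 higher (median -0.38, camera adjusted p = 1.38e-08), with mttp at -2.91 ± 0.15 and cebpa at -2.18 ± 0.15. Their median ran from -1.51 to -0.29 over the alternatives. The Nodal list had 18 of 31 lower and 2 higher (median -0.68, adjusted p = 2.66e-07), with the endoderm genes sox32, gata6 and foxa3 at -1.81 ± 0.13, -1.75 ± 0.13 and -1.43 ± 0.11. Dorsal organizer genes had 9 of 27 lower and 1 higher (median -0.41, adjusted p = 0.00107), with ism1 at -1.72 ± 0.16, and Wnt genes had 14 of 32 lower and 4 higher (median -0.40, adjusted p = 0.000963), with sp5a at -1.59 ± 0.14 and gbx1 at -1.67 ± 0.13. These 5 calls held with an estimated correlation. With values adjusted over the list alone, lower and higher genes numbered 17 and 3 for epidermal, 10 and 1 for yolk syncytial layer, 18 and 3 for Nodal, 8 and 1 for dorsal organizer and 14 and 4 for Wnt.

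4 more lists passed in this comparison but were lost with an estimated correlation. Pluripotency factors were lower (14 lower, 2 higher of 30, adjusted p = 0.00161; adjusted p = 0.103 with an estimated correlation), with sall1a at -1.22 ± 0.14. Mitotic genes were higher (15 and 5 lower of 32, adjusted p = 0.0152; adjusted p = 0.139 with an estimated correlation), with pcna at 0.94 ± 0.11, and maternal transcripts too (14 and 4 lower of 35, adjusted p = 0.0155; adjusted p = 0.337 with an estimated correlation), with btg4 at 1.39 ± 0.18. Germ plasm markers were higher (7 and 1 lower of 15, median 0.47, adjusted p = 0.0429; adjusted p = 0.0893 with an estimated correlation), with piwil1 at 1.01 ± 0.14. The germ plasm call was lost with slide as a block (adjusted p = 0.14), without combined replicate 2 (adjusted p = 0.0539) and without FoxD5 replicate 3 (adjusted p = 0.0831), within a range of 0.0112 to 0.394. The maternal call was lost with slide as a block (adjusted p = 0.0684) and without FoxD5 replicate 3 (adjusted p = 0.0757), within a range of 0.00347 to 0.337. Under 75th percentile scaling the maternal and mitotic changes were gone, with medians of 0.015 (adjusted p = 0.291) and -0.0041 (adjusted p = 0.608) against 0.29 and 0.33, and the germ plasm median was 0.38 (adjusted p = 0.0657). With the mean over probes germ plasm markers had a median of 0.12 (adjusted p = 0.394) and pluripotency factors of -0.18 (adjusted p = 0.157) against -0.35, while maternal and mitotic genes, at 0.28 (adjusted p = 0.0595) and 0.31 (adjusted p = 0.0617), kept their medians but not the call. Adjusted over the list alone, higher and lower genes numbered 3 and 15 for pluripotency, 20 and 5 for mitotic, 14 and 5 for maternal and 7 and 3 for germ plasm.

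The p53 targets did not pass (5 higher, 8 lower of 27, median -0.02, adjusted p = 0.572). The same held for BMP (adjusted p = 0.137), FGF (0.48), neuroectoderm (0.856), stress (0.485), hatching gland (0.865), apoptosis (0.118) and reference genes (0.319). Apoptosis regulators did pass as higher with slide as a block (0.58, adjusted p = 0.0463), and reference genes as lower under 75th percentile scaling (-0.84, adjusted p = 0.000434). Against the FoxD5 knockdown 8622 genes differed, 4391 higher and 4231 lower (43.3%), 1329 and 2110 of them at least 2-fold. 50.9% of them were higher, against 38.4% under 75th percentile scaling (3278 higher, 5252 lower). Slide as a block gave 7590, and leaving out combined replicate 2 gave 4876.

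The last comparison set the FoxD3 against the FoxD5 knockdown, both at 8 ng. p53 targets were higher, and the Nodal, dorsal organizer and yolk syncytial layer lists lower, in the FoxD3 knockdown. mmp2 was higher by 4.77 ± 0.40 (n = 3 against 3, limma adjusted p = 2.42e-05), bbc3 by 4.32 ± 0.29, phlda3 by 3.89 ± 0.31, lnx1 by 3.71 ± 0.26 and foxo3b, a stress-responsive forkhead factor, by 3.37 ± 0.22. sp5l was lower (-2.75 ± 0.19), with the protocadherin gene pcdh18b (-2.46 ± 0.14), igfbp1a (-2.45 ± 0.30), ckap4 (-2.42 ± 0.20) and dhrs3b, a retinaldehyde reductase (-2.32 ± 0.13).

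Of the 27 p53 targets 13 were higher and 0 lower (median 0.41, camera adjusted p = 1.02e-28, and 1.2e-11 with an estimated correlation), with sesn1 at 2.93 ± 0.12, rps27l at 2.75 ± 0.13 and casp8 at 1.44 ± 0.16. Stress genes had 7 of 30 higher and 3 lower (median 0.13, adjusted p = 0.000131), with fosab at 3.26 ± 0.19 and jun at 2.45 ± 0.16; the call was lost when probes of a gene were averaged (-0.073, adjusted p = 0.134; 1.02e-05 to 0.134 over the alternatives), and under 75th percentile scaling the median was -0.16 while the test still pointed up (adjusted p = 0.00198). The Nodal list had 16 of 31 lower and 2 higher (median -0.75, adjusted p = 1.32e-14), with the Nodal inhibitor lft2 at -1.65 ± 0.11. Dorsal organizer genes had 12 of 27 lower and 1 higher (median -0.64, adjusted p = 1.37e-11), with the forkhead gene foxa3, also in the Nodal list, at -1.21 ± 0.12. Markers of the yolk syncytial layer had 7 of 19 lower and 1 higher (median -0.48, adjusted p = 6.78e-05), with mttp at -1.42 ± 0.15 and gata6 at -1.18 ± 0.13. Wnt genes had 7 of 32 lower and 1 higher (median -0.06, adjusted p = 0.000776), with gbx1 at -1.41 ± 0.13; over the members above background in both groups the median was 0.01, opposite in sign to the test, and without FoxD3 replicate 3 the median of the whole list was 0.0084. When adjusted over the list alone, higher and lower genes numbered 15 and 1 for p53, 8 and 3 for stress, 3 and 18 for Nodal, 3 and 16 for dorsal organizer, 2 and 8 for yolk syncytial layer and 2 and 9 for Wnt.

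No call was made for maternal transcripts (6 higher, 1 lower of 35, median -0.02 with a test that pointed up, adjusted p = 0.621) or epidermal markers (4 and 3 of 27, median -0.03, adjusted p = 0.384). Nor did pluripotency (adjusted p = 0.317), BMP (0.317), FGF (0.384), neuroectoderm (0.212), germ plasm (0.527), mitotic (0.424), hatching gland (0.826), apoptosis (0.384) or reference genes (0.621) pass. The neuroectoderm list passed without FoxD5 replicate 1 (adjusted p = 0.0285; 0.0285 to 0.981 over the alternatives). Under 75th percentile scaling mitotic genes (-0.25, adjusted p = 0.00118), pluripotency factors (-0.35, adjusted p = 0.0246) and reference genes (-0.76, adjusted p = 0.000311) passed as lower, and FGF genes did with the mean over probes (-0.16, adjusted p = 0.0226). Between FoxD3 and FoxD5 knockdown 2606 genes differed, 1519 higher and 1087 lower (13.1%), with 406 and 399 differing at least 2-fold. 58.3% of them were higher, against 36.5% under 75th percentile scaling (1130 higher, 1963 lower). The count was 1395 with slide as a block, 600 in a fit of both groups only, 584 without FoxD3 replicate 2 and 1157 without FoxD5 replicate 2.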

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

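Of the tests in this part, those of slide, array and amount of morpholino for the p53 targets were chosen after the result was seen; the splits of samples were planned, and setting them apart by same-numbered pairs was chosen after. The FoxD3 and FoxD5 knockdowns, each against the same controls, differed in 6 gene lists by the direct test of the difference. The median difference, FoxD3 minus FoxD5, was 0.41 for p53 targets, -0.75 for the Nodal, mesoderm and endoderm list, -0.64 for dorsal organizer genes, -0.48 for yolk syncytial layer markers, 0.13 for stress and immediate early genes and -0.0574 for Wnt and posterior genes. The sign of these last 2 medians is not settled: stress genes were at -0.16 under 75th percentile scaling and Wnt genes at 0.0084 without FoxD3 replicate 3.

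The p53 targets were higher in the FoxD3 knockdown than in both other FoxD groups. An array or slide effect was argued against for the combined knockdown: on the 3 arrays that held both samples the list median of the combined sample minus that of the FoxD3 sample was -0.70, -0.69 and -0.50. The total amount of oligonucleotide was 8 ng in all 3 groups by the labels, and the FoxD3 minus FoxD5 median of 0.41 is the pattern itself, so it holds no test of the amount. With slide as a block the FoxD3 minus FoxD5 median was 0.40, but only 1 FoxD5 sample lay on the slide of the FoxD3 samples, so slide stays open there. A p53 response to the FoxD3 morpholino may explain the pattern as a hypothesis, to be tested with a foxd3 mutant or another morpholino, and the 4 ng of FoxD3 morpholino in the combined injection against the added FoxD5 knockdown cannot be told apart, because both change together.

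For counts of genes between groups of 3, there are 10 splits of the 6 samples, too few for a share under 0.05; in each comparison 1 split, the real one, reached the real count. Combined against FoxD3 knockdown called 9847 genes and the highest other split 2, and combined against FoxD5 called 8622 and the highest other 0. FoxD3 against FoxD5 called 2606 and the highest other split 2423. That split set FoxD3 replicate 1 with FoxD5 replicates 1 and 2 against the rest, follows neither slide nor dye, and calls nearly as many genes as the group labels do. It parts 1 of the 3 same-numbered pairs and had 5923 genes at an unadjusted limma p under 0.05, against 5559 for the group labels. The 3 other splits that part all of these pairs, as the group labels do, called 0 genes by limma, with at most 1142 at an unadjusted p under 0.05. Since pairing by number is not settled for these groups, this does not set the split with 2423 genes aside. For combined against FoxD3 the splits that part all pairs called 0 too, with at most 1812 at an unadjusted p under 0.05 against 11097. A split there that parts 1 pair had 6549. Splits that mix the groups add any difference between them to the spread within each side. Low counts in such splits were therefore to be expected and decide nothing about the group labels.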

How the results depend on the processing

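The Cy5-only fit was chosen after seeing the data; all other alternatives in this part were planned. Over 9205 alternative values of named genes 9031 kept direction and side of the threshold, 157 lost the call, 11 gained one and 6 reversed. Of 3077 values of gene lists 3008 were kept, 50 lost the call, 19 gained one and 0 reversed in the direction of the test, but the median of a called list changed sign in 4. These were stress genes in FoxD3 against FoxD5 (-0.16 under 75th percentile scaling and -0.073 with the mean over probes), Wnt genes there (0.0084 without FoxD3 replicate 3) and mitotic genes in combined against FoxD5 (-0.0041 under 75th percentile scaling). The epidermal and germ plasm lists against the control, and the p53, Nodal, dorsal organizer and yolk syncytial layer lists between FoxD3 and FoxD5 knockdown, kept their calls under every alternative run. Of the 50 lost list calls 17 were lost with an estimated correlation and 3 with probes above background in all samples. For klf4, sox2, eve1, cdx4 and other genes dim in a knockdown the fitted change rests on signal near background.

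Counts of genes moved by over 1.5 times in these cases. Without the array block Klf4 against control called 5063 and combined against FoxD3 knockdown 5819. With slide as a fixed block FoxD3 against control called 6540 and FoxD3 against FoxD5 1395, and a fit of only these groups called 600 for FoxD3 against FoxD5. The cause was not tested, apart from the fewer samples in the last fit. Called lists fell from 13 to 8 for FoxD5 against control and from 9 to 5 for combined against FoxD5 with an estimated correlation, and from 9 to 5 in the latter with the mean over probes.

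Leaving out 1 sample gave 5027 to 10173 genes for Klf4 against control, 7797 to 12310 for FoxD3, 9271 to 12409 for FoxD5 and 9037 to 11771 for the combined knockdown. It gave 3282 to 11298 for combined against FoxD3, 4876 to 9784 for combined against FoxD5 and 584 to 3664 for FoxD3 against FoxD5. The lowest counts came without control replicate 1 (Klf4, FoxD5 and combined against control), FoxD3 replicate 2 (FoxD3 against control and against FoxD5) and combined replicate 2 (combined against both single knockdowns). A group left with 1 sample was assumed to vary like the others. With Cy5 samples only, 8701, 10196 and 9950 genes were called for FoxD3, FoxD5 and combined against control.

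The 75th percentile scaling shifted the median of all genes from 0.23 to 0.40 in FoxD5 against control, from 0.04 to -0.11 in combined against FoxD5 and from 0.04 to -0.10 in FoxD3 against FoxD5, so directions of small changes there hold only relative to it. Reference genes then had medians of -0.84 and -0.76 in the last 2 comparisons and passed the test. For FoxD3 against control the median of all genes was 0.27, against 0.16 with normexp and 0.17 with the mean over probes.

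Reversed values were rpl8 in FoxD3 against FoxD5 under 75th percentile scaling (-0.22). With the mean over probes they were ctslb in FoxD5 against control (-0.58), tdrd7a and xbp1 in combined against FoxD3 (-0.14 and -0.0764), foxd3 in combined against FoxD5 (0.31) and wee2 in FoxD3 against FoxD5 (-0.22). Averages over probes differ where the probes of a gene do; beyond that the cause was not tested.

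With the replicate number as a block, 8685, 11604, 11831, 11079, 10198, 8681 and 2495 genes were called, in the order of comparisons of the report, and no count moved by over 1.5 times. The block changed no call of a list or named gene apart from klf17 in FoxD3 against control, which gained one (-0.39, adjusted p = 0.0453). In the comparisons other than FoxD3 against the combined and against the FoxD5 knockdown, same-numbered pairs off the arrays correlated at -0.297 to 0.209.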

Other observations

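Tests of slide, of early zygotic genes and of Cy5 samples alone in this part were chosen after the data were seen; those of the dye effect in the Klf4 comparison and of late-onset genes were written before, though the check that voids the late-onset test was added after its value was known. Within the FGF list targets of the pathway parted: etv5a rose in all 4 knockdowns, by 2.07 ± 0.12 with FoxD5 and 2.19 ± 0.12 with the combined morpholinos besides the values above, while spry2 fell in all 4, with -1.80 ± 0.14 in the combined knockdown. klf2a, a flow-responsive Krüppel-like gene, rose by 2.08 ± 0.11 in the FoxD5 and 1.48 ± 0.11 in the combined knockdown. Among apoptosis regulators birc2 was at -1.73 ± 0.16 with FoxD5 and -2.64 ± 0.16 in the combined knockdown, where bik stood at -3.46 ± 0.37. Against the FoxD3 knockdown the survival gene mcl1a was higher in the combined knockdown by 1.45 ± 0.13, and against the FoxD5 knockdown the DNA repair gene parp1 by 1.71 ± 0.23.

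The list of reference genes passed in no comparison with the control, apart from FoxD3 and FoxD5 with the mean over probes, but single members moved. tbp, the TATA-binding protein, rose in all 4 knockdowns, by 1.17 ± 0.09 with Klf4, 1.68 ± 0.10 with FoxD3, 1.06 ± 0.09 with FoxD5 and 1.37 ± 0.09 with both. b2m, the light chain of class I MHC, was at -3.56 ± 0.29, -3.63 ± 0.27 and -2.55 ± 0.27 in the FoxD3, FoxD5 and combined knockdowns. These calls and directions held under all scalings run. Between FoxD3 and FoxD5 knockdown ventral foxi1 was higher by 1.35 ± 0.10 and the apelin receptor gene aplnrb by 2.16 ± 0.17, while fgf8a was lower (-1.22 ± 0.12).

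In all 4 knockdowns maternal RNAs were higher and epidermal and enveloping layer genes lower than in the controls, with a gap between both list medians of 2.04 (Klf4), 2.59 (FoxD3), 2.48 (FoxD5) and 3.54 (combined), though with an estimated correlation the maternal call was lost for FoxD3 (adjusted p = 0.0705) and FoxD5 (adjusted p = 0.0674). Dye was argued against as the whole cause, since Cy5 samples alone kept at least 98% of the gap in the FoxD groups, and the dye effect had a gap of 0.0488 between the lists against an uncorrected Klf4 gap of 2.15. Slide stays open for the FoxD groups, because the 93% or more kept with slide as a block rests on 1 linking sample, but Klf4 and control samples shared arrays. Controls further along in development may account for the pattern: late-onset genes had medians of -0.04, 0.08, 0.35 and -0.26, and although FoxD5 met the bound set against this, 6 of the 18 tested rose and 4 fell there, so the median decides nothing. Less zygotic transcription as a whole is open too. Early zygotic genes had medians of -0.0695, -1.04, -0.55 and -1.03, with 2 of 14 called higher and 4 lower in the Klf4 knockdown. All 14 also stand in the dorsal organizer, yolk syncytial layer, Nodal, BMP, Wnt or FGF list. Their medians therefore give no separate reading of zygotic transcription as a whole. The design gives no measure of stage beyond the hour of collection to separate both explanations from an effect of the knockdowns.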
